A study of Solanum tuberosum with 72 samples.

How the data were processed

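Transcript levels were measured on 72 spotted complementary DNA microarrays of potato seedlings, variety Gilroy. Per the labels, seedlings grew from true potato seed for 5 weeks on rafts floating on hydroponic medium, under 16 h of light and 8 h of dark at 25 °C. They then met cold (4 °C), heat (35 °C), salt or no stress for 3, 9 or 27 h, and leaves and roots were collected. The salt dose is stated in conflicting ways: the labels give 150 mM NaCl where they name the sample's source and 100 mM NaCl in the description of the treatment, and it was not settled here. Per the labels, a sample held 6 plants from 2 boxes, the reference was pooled from 6 boxes, and the experiment was carried out independently 3 times. The 24 groups (2 tissues, 4 treatments, 3 times) held 3 arrays each.

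Each array compared 2 RNAs. Per the labels, the query (the stressed plants, or on the no-stress arrays a further control sample) carried Cy3, the reference (control plants of the same tissue and time) carried Cy5, and no dye swap was made. The deposited values are log2 ratios, 1 per spot and array, that the authors had already processed. Between -1 and 1 all of them equal the log2 of a ratio with 2 decimals within 0.0016, so they had been rounded. Array medians lay between 0 and 0.014. The background correction, the normalization, the scanner settings and the filter that left spots empty are not given in the sources used here. Of 32448 spots, 10520 had no value on any array and 9229 had a value on every array.

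The direction of the ratio is not written in the table. It was read as query over reference, which makes positive values higher in stressed plants, and this is called likely rather than settled. The basis is the naming of the channels in the labels, together with passing cold values of UCP (an uncoupling protein), AOX (alternative oxidase) and StWIPK (a wound-induced protein kinase), all of which are positive and are genes known to respond to cold or injury. Other cold values of UCP and AOX did not pass. This basis was chosen after the values were seen, so their sign is no independent finding. The titles name the control before the stress. A rule fixed beforehand was to use the lists of small heat-shock proteins and of larger heat-shock chaperones, but neither list matched a clone. For that case the rule gave no direction unless the labels, files or dyes settled it, so calling the direction likely departs from it. Had the ratio been reversed, every higher and lower would trade places. The lowest correlation between any 2 of the arrays was -0.33, between leaf cold 27 h replicate 3 and leaf heat 9 h replicate 2, and it was the only 1 of 2556 pairs under -0.3. Since dyes are stated and cold and heat could oppose each other, the direction was kept.

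The spot order fits a layout of 48 blocks of 26 by 26 spots in which each clone was printed at 2 spots. All 905 annotated pairs carried the same accessions at both spots, and the median correlation of the 2 spots over arrays was 0.93 for annotated clones and 0.79 for the others, against -0.01 for spots paired at random. The 2 spots were averaged. This gave 11037 clones with a value, called probes here, of which 6140 had one on every array. The layout was inferred from the files.

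Gene names came from the platform annotation that was given with the data. Where a gene identifier matched, the symbol and synonyms were taken from the RefSeq table of the potato assembly SolTub_3.0, which was used for names alone. Of the printed clones, 905 were annotated, 815 with 1 gene symbol and 90 with several. Among the clones with a value, 10156 had no annotation. Only 363 clones of 197 genes carried a gene name rather than a locus number, and 357 of these clones, from 195 genes, had a value. Clones with several symbols were not named. Most called probes therefore have no name here.

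Before the data were examined, the comparisons, tests, gene lists, alternatives and the rule for named genes were fixed. Each stress group was compared with the no-stress arrays of the same tissue and time, so that effects of dye and reference cancel. The test was limma's moderated test (limma 3.58.1, R 4.3.3), two-sided, on log2 ratios, fitted over all 36 arrays of a tissue without a block. A probe was tested where at least 2 of the 3 arrays of each group had a value, and Benjamini-Hochberg adjusted p under 0.05 within a comparison was called. A further 3 tests asked whether the mean effect over times differed between leaf and root (all 72 arrays), and 6 asked whether the effect at 27 h differed from that at 3 h. Standard errors (SE) are those of the moderated fit.

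Named genes were chosen by this rule. Per tissue and stress, 1 probe per gene was taken, with the largest mean absolute log2 value over times. The 8 highest and 8 lowest genes by mean log2 value among those passing in 1 direction at 2 or more times were named, filled up with genes passing at 1 time. Up to 2 members per direction of each gene group were added. The 30 lists fixed beforehand were matched to gene symbols and their synonyms. Of these, 24 matched no clone and 6 matched at least 1, and only the list of co-chaperones and DnaJ proteins, 8 clones of 1 gene, reached the 5 probes needed for a test. A further 16 groups of gene symbols were written after the annotation had been seen and before any result per gene was computed. Groups were tested with limma's cameraPR at a preset inter-gene correlation of 0.01, and with the correlation estimated from the residuals as an alternative. None of the 37 group calls made at the preset correlation held with the estimated one, so each group statement rests on its counts of passing members, which count several clones of a gene separately. These counts were not tested against the share of all tested probes that was called, which is given with each comparison.

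The test was tried on simulated data for leaf heat at 9 h, over 9448 probes. With 50 probes changed at each size, 34% of those with a log2 change of 0.5, 86% at 1, 100% at 2 and 98% at 4 were called in the right direction, and 6.47% of the 170 calls were unchanged probes. The simulated values were independent normal draws with 1 spread per probe for all groups, which is the model of the test itself. They held no arrays of uneven quality and no deviations shared by replicate number. The simulation therefore does not show the error rate on the real arrays. The alternatives were: subtracting array medians, a replicate block, stress arrays against 0, only the contrast's groups in the fit, only probes with a value on every array, array weights, leaving out each array, and, for groups, 1 value per gene. Using only 1 spot per clone, and leaving out each array in the group tests, were chosen after seeing the data. Overlaps between stresses of a tissue and time share the no-stress arrays, and the values expected from sharing were simulated. The number of arrays limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.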

Results

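The data hold leaf and root expression of potato seedlings under cold, heat and salt at 3, 9 and 27 h, with control-against-control arrays at the same tissues and times, 3 arrays per group. The series is described as a study of adaptation to these stresses. Replicate arrays of a group correlated over probes with r from 0.65 to 0.86 in leaf cold, 0.08 to 0.53 in leaf heat, 0.35 to 0.82 in leaf salt and 0.16 to 0.47 in leaf no stress. The same range was 0.77 to 0.91 in root cold, 0.58 to 0.69 in root heat, 0.65 to 0.78 in root salt and 0.34 to 0.67 in root no stress. As background, the no-stress arrays alone gave 6, 71 and 1 probes different from 0 in leaf at 3, 9 and 27 h, and 462, 295 and 133 in root. Of the 10422 probes tested in 1 or more comparisons, 6865 were called at least once. Log2 differences below are stress minus no stress, with positive values likely meaning higher in stressed plants. Each is the value of 1 probe. Of 83 pairs of a gene named by rank and a comparison, 38 had another tested probe of the gene, and in 22 of these every other probe was called the same way.

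**Figure D1:**
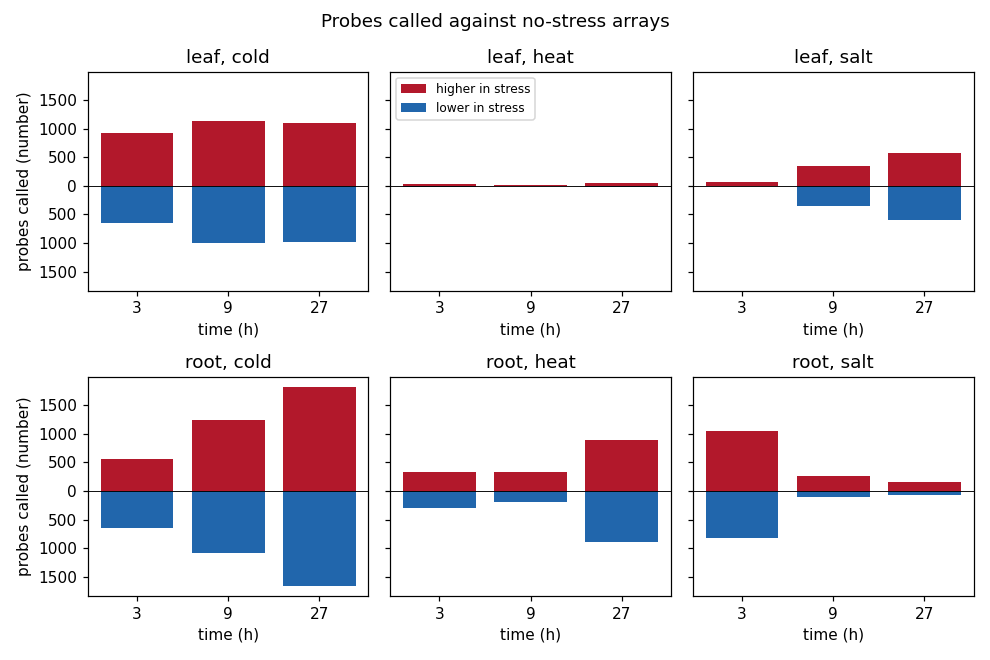
Number of probes called at adjusted p under 0.05 against the no-stress arrays (y axis, count; above 0 positive log2 differences, below 0 negative ones) by time in h (x axis), 1 panel per tissue and stress, 3 against 3 arrays. Leaf salt counts were 77, 703 and 1174 at 3, 9 and 27 h, and root salt counts were 1884, 381 and 217.

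In cold leaves ChtA1, a chitinase, was 4.52 log2 units higher at 27 h (SE 0.47, limma adjusted p 1.55e-07). RSI5 was 2.90, 3.13 and 2.84 higher at 3, 9 and 27 h (SE 0.32), and STUGE45, a UDP-glucose epimerase of sugar nucleotide metabolism, was 1.91, 3.06 and 2.23 higher (SE 0.29). CCoAOMT, an enzyme of lignin precursor synthesis, rose by 2.21 at 9 h and 2.22 at 27 h (SE 0.30). StWIPK rose at all times, by 2.40 at 3 h (SE 0.30) and 0.98 at 27 h. AMYA1, an alpha-amylase, rose by 1.72 at 9 h (SE 0.28), and the WRKY transcription factors STWRKY8 and StWRKY16 rose at every time.

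Lower transcripts in cold leaves included psbP, of the oxygen-evolving complex, at -1.36 at 9 h (SE 0.23), and TPT, the chloroplast triose phosphate translocator, at -1.06 at 3 h (SE 0.21). TK, a transketolase, was at -0.92 at 27 h (SE 0.21), MIP2 at -1.06 at 27 h and DHAR2, a dehydroascorbate reductase, at -0.88 at 9 h. LOX-H1, a lipoxygenase, was at -1.83 at 9 h (SE 0.56), LPD2 at -0.98 at 3 h and RPE, ribulose-phosphate epimerase, at -0.77 at 3 h. Calls ended for LOX-H1 without cold replicate 2 or no-stress replicate 3 (adjusted p 0.087 and 0.0541), and for LPD2 and RPE without cold replicate 1 (0.0602 and 0.0951). The call of RPE also ended with only the contrast's groups in the fit (0.0808). Of UCP, 1 probe rose by 0.53, 0.47 and 0.80 (SE 0.16), while the other passed at 27 h (0.69) and not at 3 or 9 h (0.40 and 0.38, adjusted p 0.0757 and 0.0816), and METK2, an S-adenosylmethionine synthetase, rose by 1.21 at 9 h (SE 0.20). The other probes of TPT (0.15), TK (-0.50) and RPE (-0.61) did not pass.

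Of the 14 photosynthesis and photorespiration probes tested in leaf at 27 h of cold, 8 fell, 1 rose and 5 did not pass (adjusted p 0.00143 at the preset correlation; adjusted p = 0.702 with an estimated correlation). The probe that rose was 1 of PSBR, of which 2 other probes fell. Of 10 defence probes, 6 rose, 0 fell and 4 did not pass at 27 h (adjusted p 0.00143, and adjusted p = 0.702 with an estimated correlation). The 16 protein kinase and phosphatase probes gave 8 higher, 0 lower and 8 not passing at 27 h (0.00251, and adjusted p = 0.594 with an estimated correlation). Methionine, polyamine and sulfur amino acid enzymes gave 14 higher, 2 lower and 19 not passing among 35 probes at 9 h (0.00366, and adjusted p = 0.635 with an estimated correlation). These are clones of 11 genes, and with 1 value per gene the call ended (adjusted p 0.133). SAMDC, S-adenosylmethionine decarboxylase, was among those that rose. Among 23 mitochondrial probes 9 rose, 1 fell and 13 did not pass at 27 h (0.00598, and adjusted p = 0.765 with an estimated correlation), with Aconitase at 0.90 (SE 0.16). That call also ended with 1 value for each of the 13 genes (0.154) and with stress arrays against 0 (0.056). All 18 stress comparisons used limma over 36 arrays of the tissue. In leaf cold, 1572 of 9408 probes were called at 3 h (922 higher, 650 lower), 2119 at 9 h (1128 and 991) and 2074 at 27 h (1099 and 975). These were 16.71, 22.5 and 21.53% of all tested probes, the shares to set beside the group counts. The count at 3 h was 895 without cold replicate 1, and at 27 h it was 1374 without cold replicate 2. With only the contrast's groups in the fit it was 1296 at 9 h.

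**Figure D2:**
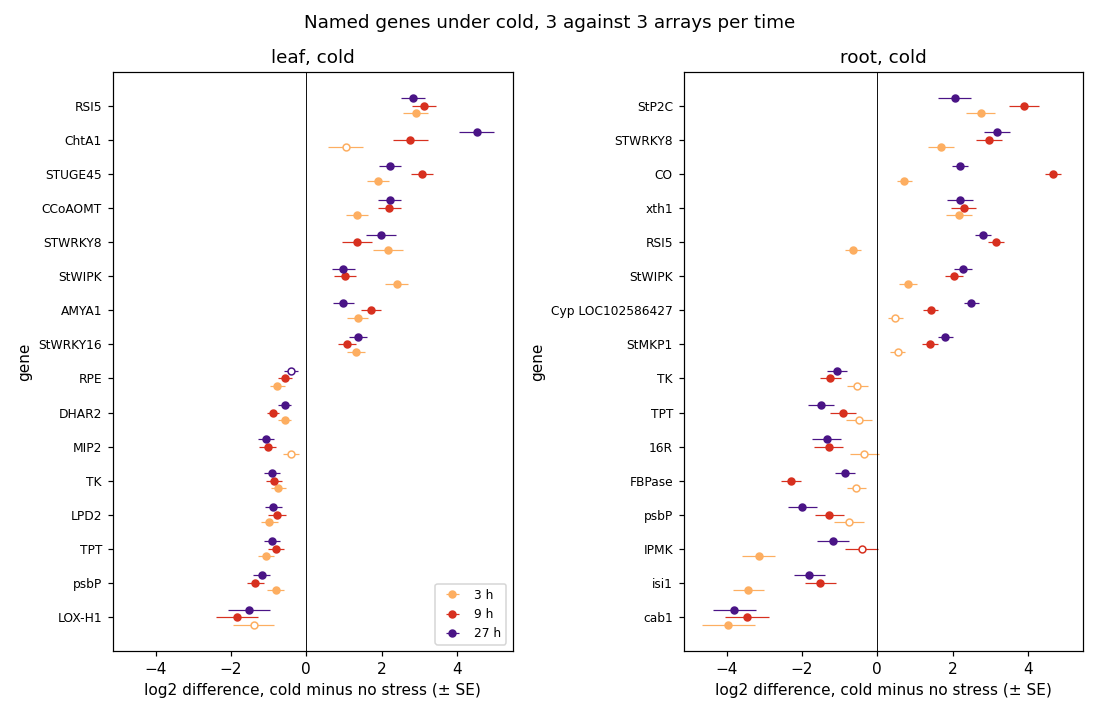
Log2 difference, cold minus no stress (x axis, log2 units; bars are SE of the limma fit, 3 against 3 arrays), of the genes named by rank in leaf and root (y axis). Filled points passed adjusted p under 0.05 and open points did not. ChtA1 reached 4.52 in leaf at 27 h and CO reached 4.67 in root at 9 h.

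In cold roots CO, a CONSTANS-type regulator, rose by 4.67 at 9 h (SE 0.21, adjusted p 1.42e-15), against 0.72 at 3 h and 2.20 at 27 h. StP2C, a protein phosphatase 2C, rose by 3.90 at 9 h (SE 0.39), STWRKY8 by 3.18 at 27 h (SE 0.35), and xth1, a xyloglucan endotransglucosylase of the cell wall, by 2.17 to 2.29 at the 3 times. RSI5 was lower at 3 h (-0.63, SE 0.21) and higher at 9 and 27 h (3.16 and 2.81). The regulator NAC2 was likewise lower at 3 h and higher at 9 and 27 h, by 1.38 and 2.47 (SE 0.34). StWIPK and StMKP1, a MAP kinase phosphatase, reached 2.28 (SE 0.24) and 1.81 (SE 0.21) at 27 h. Of Cyp LOC102586427, 1 probe was at 2.50 at 27 h (SE 0.20), while 3 others fell, to -0.56, -0.67 and -0.74, so the gene has no single direction here. AOX rose by 1.32 at 27 h (SE 0.39), while UCP did not pass, with -0.22, -0.15 and 0.24 at 3, 9 and 27 h. Cab1, a chlorophyll a/b-binding protein, was at -3.95, -3.45 and -3.79 (SE 0.71, 0.58 and 0.58). Further lower genes were isi1 at -3.43 at 3 h (SE 0.41), IPMK at -3.15 at 3 h (SE 0.43), and psbP at -1.99 at 27 h (SE 0.39). FBPase, a fructose-bisphosphatase, was at -2.29 at 9 h (SE 0.26), TPT at -1.49 at 27 h, TK at -1.25 at 9 h and 16R at -1.34 at 27 h. The call of 16R ended without no-stress replicate 3 (adjusted p 0.108) or with only the contrast's groups in the fit (0.0632), and the other probes of 16R (-0.07) and TPT (-0.11) did not pass.

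Photosynthesis probes in cold roots numbered 0 higher and 11 lower of 22 at 9 h, and 2 higher and 17 lower of 23 at 27 h (adjusted p 0.000846 and 0.00143, and adjusted p = 0.702 with an estimated correlation at both). Both probes that rose at 27 h were of PSBR, a photosystem II protein, the higher at 2.30 (SE 0.29), but 3 other probes of this gene fell, to -0.68, -0.75 and -0.97. Kinase and phosphatase probes gave 9 higher, 1 lower and 6 not passing of 16 at 27 h (0.00251, and adjusted p = 0.398 with an estimated correlation). Methionine and polyamine enzymes gave 16 higher, 3 lower and 11 not passing of 30 (0.0125, and adjusted p = 0.705 with an estimated correlation), including METK2 at 1.81 (SE 0.27) and SAMDC at 1.55 (SE 0.23). These were clones of 11 genes, and with 1 value per gene the median fell from 0.49 to 0.24 and the call ended (0.286). Starch and sucrose genes gave 0 higher, 4 lower and 19 not passing of 23 at 3 h (0.026, and adjusted p = 0.594 with an estimated correlation), a call that ended without cold replicate 2 (0.0537) or no-stress replicate 2 (0.0543), with 1 value for each of 16 genes (0.0891) and against 0 (0.149). GBSS, granule-bound starch synthase, was at -0.94, 1.10 and -0.86 (SE 0.21), passing at all times. In root cold 1200 probes were called at 3 h (561 higher, 639 lower), 2328 at 9 h (1246 and 1082) and 3476 at 27 h (1818 and 1658), and 216 probes were called in both directions at different times. Calls made up 13.15, 26.25 and 38.89% of all tested probes at 3, 9 and 27 h. The count at 3 h was 762 without cold replicate 2 and 776 without cold replicate 3.

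Heat gave few calls in leaves: 63 at 3 h (36 higher, 27 lower), 17 at 9 h (14 and 3) and 64 at 27 h (43 and 21). That is 0.67, 0.18 and 0.64% of all tested probes. Lea, a late embryogenesis abundant protein gene, was at -1.31 at 9 h (SE 0.24, adjusted p 0.0149) and -0.99 at 27 h. agpS3, of ADP-glucose pyrophosphorylase in starch synthesis, was at -0.94 at 27 h (SE 0.18, 0.0115), SI1 rose by 0.71 at 27 h (SE 0.14, 0.0115), METK1 rose by 0.72 at 27 h (SE 0.16) and GAPDH fell by 0.56 at 3 h (SE 0.12). The 6 other probes of METK1, the 7 of GAPDH and 1 of the 2 of SI1 did not pass. Of 15 glycolysis probes at 3 h, 0 rose, 1 fell and 14 did not pass (0.00442, and adjusted p = 0.594 with an estimated correlation), and of 6 hormone response probes at 9 h none passed (0.0125, and adjusted p = 0.398 with an estimated correlation). The glycolysis call ended with 1 value for each of 6 genes (0.384), and the hormone call with stress arrays against 0 (0.209). Calls of Lea at 9 h ended without heat replicate 1 (adjusted p 0.0869), heat replicate 2 (0.0588) or no-stress replicate 1 (0.139), those of agpS3 without heat replicate 1 (0.141) or no-stress replicates 1 or 3 (0.0512, 0.0599), and those of SI1 without heat replicate 1 (0.0957) or no-stress replicates 2 or 3 (0.0782, 0.0556). With only the contrast's groups in the fit, limma called 0 probes at 9 h and 0 at 27 h, with 896 and 1080 at an unadjusted p under 0.05. The calls at these times, among them Lea (0.28), agpS3 (0.155), SI1 (0.228) and METK1, thus rest on the spread estimated over all groups of the tissue. The counts moved without single arrays: at 3 h to 23, 14 and 12 without no-stress replicates 1, 2 and 3, and 7 and 41 without heat replicates 1 and 3. At 9 h they moved to 1, 9 and 3 without no-stress replicates 1, 2 and 3, and 1 and 6 without heat replicates 2 and 3, and at 27 h to 20, 32 and 9 without no-stress replicates 1, 2 and 3, and 9 and 126 without heat replicates 1 and 2. Other settings raised the counts at 3, 9 and 27 h. They were 138, 46 and 120 with the replicate block, 181, 244 and 516 with array weights, and 886, 682 and 568 against 0.

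In roots heat called 638, 519 and 1790 probes (339, 331 and 900 higher, 299, 188 and 890 lower). As shares of all tested probes these were 7.11, 5.83 and 19.94% at 3, 9 and 27 h. VPE2 was at -2.41 at 3 h (SE 0.46, adjusted p 0.00258) and passed at all times. SGA was at -2.67 at 27 h (SE 0.58), agpS3 at -1.56 at 27 h (SE 0.22), CO at -1.33 at 3 h and -1.32 at 27 h (SE 0.21), GCVT, of glycine decarboxylase, at -1.41 at 27 h (SE 0.21), GBSS at -1.38 at 27 h (SE 0.21) and FBPase at -1.19 at 9 h. Lea was at -0.87 at 27 h. Higher genes were AMYA1 at 1.15 (SE 0.21), SI1 at 1.08 (SE 0.16), eIF5A5, a translation factor, at 0.96 and StSSR1 at 0.95, all at 27 h. ARD, of methionine salvage, was at 0.72 and DHAR at 0.76 at 9 h (SE 0.17 and 0.19), DHAR2 at 0.60 and TYKY2 at 0.52 at 27 h. The other probes of DHAR (0.11) and DHAR2 (0.56) did not pass. Photosynthesis probes gave 0 higher, 13 lower and 10 not passing of 23 at 27 h (1.74e-07, and adjusted p = 0.594 with an estimated correlation), including cab1 at -3.32 (SE 0.55) and PSBO at -1.77. The median log2 ratio over the group on single arrays was -0.972, 0.0192 and 0.0275 in replicates 1, 2 and 3 at 3 h, -0.905, 0.105 and -0.144 at 9 h, and -1.52, -0.556 and -0.632 at 27 h. Shoot tissue mixed by chance into some root samples could give such differences between replicates, and was not tested for heat. Of 13 glycolysis probes at 9 h, 4 fell, 0 rose and 9 did not pass, and the group's adjusted p of 0.048 rose to between 0.0768 and 0.126 without no-stress replicates 1 or 3 or any heat replicate (adjusted p = 0.723 with an estimated correlation). It was 0.241 with 1 value for each of 6 genes and 0.0514 with array medians subtracted.

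Single arrays moved the root heat counts. Without heat replicate 1 they were 283, 138 and 703 at 3, 9 and 27 h. At 3 h the count was 360 without heat replicate 2, and 384 and 362 without no-stress replicates 2 and 3. At 9 h it was 261 and 313 without no-stress replicates 1 and 2, and at 27 h it was 1137 and 1105 without no-stress replicates 2 and 3. Calls of ARD ended without heat replicate 1 (0.135) or no-stress replicate 1 (0.0554) and those of DHAR without heat replicates 1 or 3 (0.101, 0.0585) or no-stress replicate 2 (0.0909). DHAR2 lost its call without heat replicate 1 (0.108) or no-stress replicate 2 (0.057), and FBPase without heat replicate 1 (0.0682). With only the contrast's groups in the fit the counts were 257, 308 and 125. That ended the calls of StSSR1, eIF5A5, SGA and Lea (all 0.0513), AMYA1 (0.0564), DHAR2 (0.0941) and TYKY2 (0.0706) at 27 h, and of ARD (0.0715) and DHAR (0.0568) at 9 h. DHAR also lost its call with only the first spot of each clone (0.0671).

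Salt gave calls in leaves that grew in number with time, 77 at 3 h (72 higher, 5 lower), 703 at 9 h (350 and 353) and 1174 at 27 h (572 and 602). Their shares of all tested probes were 0.81, 7.45 and 11.85%. ChtA1 was 2.78 higher at 9 h and 3.48 higher at 27 h (SE 0.52, adjusted p 3.25e-05 at 27 h). RSI5 rose by 1.64, 2.04 and 2.25 (SE 0.32) and STUGE45 by 1.32, 1.51 and 2.04 (SE 0.29). HPL, hydroperoxide lyase of oxylipin synthesis, rose by 1.56 and 2.02 at 9 and 27 h (SE 0.34), SBE1, a starch branching enzyme, by 1.44 at 27 h (SE 0.18), CCoAOMT by 1.26 at 27 h, sus4, sucrose synthase, by 1.21 at 9 h (SE 0.20), and TRI, tropinone reductase, by 1.12 at 9 h. Lower genes included InvCD141, an invertase, at -1.74 at 27 h (SE 0.33), GCVT at -1.25, FBPase at -1.18 (SE 0.30), agpS3 at -1.02, LPD2 at -1.04 and PIN-II, proteinase inhibitor II, at -1.43 (SE 0.26), all at 27 h. MIP2 and IAA3, an Aux/IAA repressor, were at -1.06 and -0.66 at 9 h. The 3 other probes of PIN-II (-0.41, -0.39 and -1.40), 1 of the 2 of sus4 (0.20) and the other of TK (-0.58, at 27 h) did not pass. Photosynthesis probes gave 0 higher, 3 lower and 11 not passing of 14 at 27 h (0.0016, and adjusted p = 0.702 with an estimated correlation), including TK at -0.78 (SE 0.21). The only testable preset list, 6 DnaJ probes of 1 gene at 3 h, gave 0 calls in the test over all probes and 0 adjusted over the list alone, with a median of 0.24 (adjusted p 0.0112 over 6 such tests at the preset correlation, and adjusted p = 0.403 with an estimated correlation). Calls ended for FBPase without salt replicate 3 (0.0616), TRI without no-stress replicate 2 (0.0916), and IAA3 without salt replicate 2 or no-stress replicate 3 (0.128, 0.114). With only the contrast's groups in the fit, TRI (0.0658), MIP2 (0.0512) and IAA3 (0.0672) lost theirs. The count at 3 h was 42 without no-stress replicate 2. At 9 h it was 395, 383 and 300 without no-stress replicate 2, no-stress replicate 3 and salt replicate 2, and at 27 h it was 777 without no-stress replicate 2.

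In roots the salt counts ran from 1884 at 3 h (1058 higher, 826 lower) to 381 at 9 h (270 and 111) and 217 at 27 h (153 and 64). Their shares of all tested probes were 21.46, 4.33 and 2.38%. STUGE45 rose by 2.39 at 3 h (SE 0.30, adjusted p 4.34e-06) and 1.53 at 27 h, RSI5 by 2.14, 2.08 and 1.46 (SE 0.21), and CCoAOMT at all times, by 1.66 at 3 h and 1.18 at 27 h (SE 0.27). HPL rose by 1.42 at 27 h (SE 0.27), StMPK4, a MAP kinase, by 1.03 at 3 h (SE 0.21), ChtA1 by 2.59 at 9 h (SE 0.64), ARD by 0.82 and FDH, formate dehydrogenase, by 0.71, both at 9 h. Patatin-01 was at -1.74 at 9 h (SE 0.43), TPT at -1.19 at 3 h, FLS, flavonol synthase, at -1.11 at 27 h (SE 0.27), 16R at -1.29 at 27 h, agpS3 at -0.84, PBF-2 at -0.81 and PCS-2-1 at -0.78 at 3 h, and IAA2 at -0.75 at 9 h. At these times the 3 other probes of FLS (-0.60, -0.02 and 0.11), 2 of the 4 of PCS-2-1 (-0.03 and -0.02) and the others of ChtA1 (2.17), 16R (-1.13) and TPT (-0.42) did not pass, and 1 of these FLS probes had risen at 3 h (0.60). Methionine and polyamine probes gave 10 higher, 3 lower and 16 not passing of 29 at 3 h (0.0207, and adjusted p = 0.734 with an estimated correlation), a call that ended without salt replicate 3 (0.0625) or with 1 value for each of 11 genes (0.154). METK2 was at 1.45 (SE 0.27) and MS, methionine synthase, at 1.18 (SE 0.24) there. Starch and sucrose probes gave 7 higher, 0 lower and 17 not passing of 24 at 9 h (0.0283, and adjusted p = 0.594 with an estimated correlation), ending without no-stress replicate 1 (0.0826), with 1 value for each of 17 genes (0.2) or against 0 (0.391), with AMYA1 at 1.08 and sus4 at 1.07.

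Several root salt calls depended on single arrays. The count at 3 h was 1176 without no-stress replicate 2. At 9 h it was 192 and 240 without no-stress replicates 1 and 3, and 252, 237 and 215 without salt replicates 1, 2 and 3. At 27 h it was 103 and 114 without no-stress replicates 1 and 2, and 115 and 87 without salt replicates 1 and 3. ChtA1 ended without no-stress replicate 1 (0.0838) or salt replicates 2 or 3 (0.0541, 0.0845), Patatin-01 without no-stress replicate 3 (0.135) or salt replicate 3 (0.129), and FLS without no-stress replicates 1 or 2 (0.0999, 0.09) or salt replicate 3 (0.19). FDH ended without no-stress replicates 2 or 3 (0.124, 0.134) or salt replicates 1 or 2 (0.211, 0.0675), IAA2 without no-stress replicate 1 (0.0637) or salt replicate 3 (0.153), and PCS-2-1 without no-stress replicates 1 or 2 (0.152, 0.0679) or salt replicates 2 or 3 (0.129, 0.0834). With only the contrast's groups in the fit the count was 1040 at 3 h and 329 at 27 h, and FDH (0.0735), Patatin-01 (0.0938), FLS (0.0628) and IAA2 (0.0599) lost their calls. FDH and IAA2 also lost theirs with stress arrays against 0 (0.0898, 0.0751), and PCS-2-1 with only the first spot of each clone (0.112).

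The effect of cold, averaged over times, differed between leaf and root for 1618 probes, that of heat for 132 and that of salt for 329. Leaf minus root was -1.70 for CO under cold (SE 0.21, adjusted p 2.24e-08), with a mean effect of 0.83 in leaf and 2.53 in root. By time, CO was at 1.35 in leaf and 0.72 in root at 3 h, 1.77 and 4.67 at 9 h, and -0.62 (not passing) and 2.20 at 27 h. The other order at 3 h was not tested, since tissues were compared only on the mean over times. The difference was 2.04 for ChtA1 (SE 0.48), 1.18 for RSI5 (SE 0.23) and 1.16 for AMYA1 (SE 0.20) under cold. For RSI5 the average came from 3 h (2.90 in leaf, -0.63 in root), with 3.13 and 3.16 at 9 h and 2.84 and 2.81 at 27 h. Leaf minus root was 1.91 for SGA under heat (SE 0.37, adjusted p 0.00349). Under salt PHA1, a plasma membrane proton pump, differed by -0.57 (SE 0.11, adjusted p 0.000416), with 0.48 in root and -0.09 in leaf. The heat count was 75 without root heat 27 h replicate 1, 263 without root heat 27 h replicate 3 and 86 without root heat 9 h replicate 1.

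The effect at 27 h differed from that at 3 h for 1878 probes in root cold, 247 in root salt, 15 in root heat, 125 in leaf cold and 12 in leaf salt. In leaf heat 0 probes differed by limma's adjusted p and 199 had an unadjusted p under 0.05. RSI5 in root cold differed by 3.44 (SE 0.30, adjusted p 4.56e-09) and NAC2 by 3.48 (SE 0.48). In leaf cold ChtA1 differed by 3.47 (SE 0.67, adjusted p 0.00654) and CO by -1.97 (SE 0.42), from 1.35 at 3 h to -0.62 at 27 h. PPS1 differed by -1.50 in root salt (SE 0.29, adjusted p 0.00589), and GBSS by 1.32 (SE 0.30). The leaf cold count was 76 without cold 27 h replicate 2, 69 without cold 3 h replicate 1, 83 and 64 without no-stress 27 h replicates 1 and 2, and 67 and 72 without no-stress 3 h replicates 1 and 2. The root salt count was 100 and 147 without no-stress 27 h replicates 1 and 2, 97 without no-stress 3 h replicate 2, 137 and 122 without salt 27 h replicates 1 and 2, and 123 without salt 3 h replicate 2. For leaf salt it was 2, 0 and 7 without no-stress 27 h replicates 1, 2 and 3, and 0, 1 and 3 without no-stress 3 h replicates 1, 2 and 3. It was 0 and 4 without salt 27 h replicates 2 and 3, and 0, 0 and 4 without salt 3 h replicates 1, 2 and 3. Where limma called 0 there, 580 to 759 probes had an unadjusted p under 0.05. For root heat it was 3 and 6 without no-stress 27 h replicates 2 and 3, 5, 3 and 5 without no-stress 3 h replicates 1, 2 and 3, 9, 7 and 87 without heat 27 h replicates 1, 2 and 3, and 71, 3 and 4 without heat 3 h replicates 1, 2 and 3.

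Leaf responses to cold and salt overlapped. At 27 h 353 probes were higher and 447 lower under both, where independent lists of those sizes would share 65.2 and 60.6, and 2 were opposite. Unchanged groups with the same no-stress arrays gave 0 shared calls on average in simulation, a value that sets no scale, because groups without changes are expected to have hardly any calls to share. Effects correlated across probes with r 0.778 (simulated 0.499), and their covariance was 0.179 against a simulated 0.0226. The simulated r follows from sharing controls alone and sets no scale for r once real effects add variance. Only the covariances can be set against the simulation. At 3 h r was 0.531 (simulated 0.501), and the covariance was 0.0689 against 0.0224. Leaf cold and heat at 9 h correlated at -0.0667 (simulated 0.499), with a covariance of -0.00851 against 0.0224, and 0 shared calls in 1 direction with 5 opposite. In roots at 27 h cold and heat shared 191 higher and 399 lower probes (179 and 168 for independent lists) and had 274 opposite. There r was 0.269 (simulated 0.496), and the covariance was 0.0955 against 0.0233. With 3 no-stress arrays no split leaves at least 2 arrays in each part, so the shares were not computed on separate no-stress arrays and part of each excess may come from sharing them. Leaf and root shared 502 higher and 412 lower probes under cold at 9 h (151 and 113 for independent lists), with 37 opposite.

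**Figure D3:**
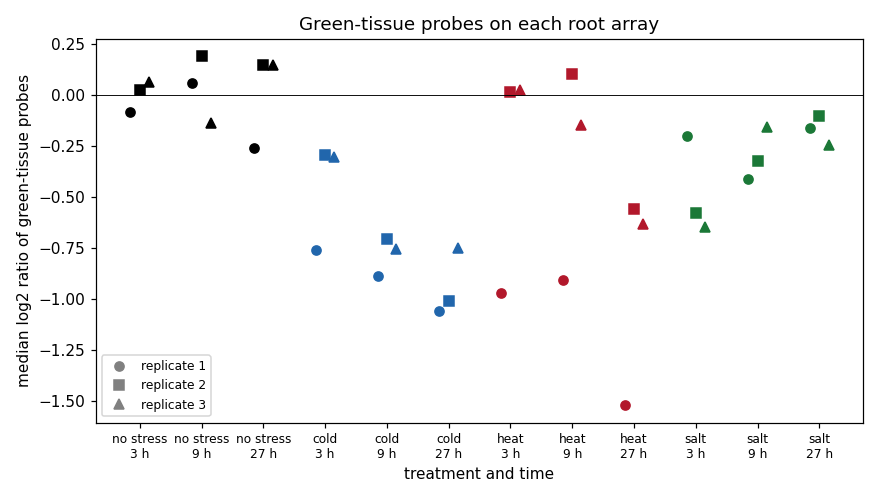
Median log2 ratio of the photosynthesis and photorespiration probes (y axis, log2 units) on each root array, by treatment and time (x axis), 1 symbol per replicate. No-stress arrays lay between -0.26 and 0.192, cold arrays at 9 and 27 h between -1.06 and -0.704, and salt arrays between -0.644 and -0.1. Heat replicate 1 lay below the other 2 heat replicates at all 3 times.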

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

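The tests chosen only after the result was seen are those of replicate noise in the leaf heat arrays and of shoot tissue in the root cold samples, together with the group tests that left out single arrays. Tests of a difference between tissues or times picked out the results that follow. The effect of a stress differed between leaf and root for 1618 probes under cold, 132 under heat (75 to 263 without 1 array) and 329 under salt. Over all tested probes these were 20.03, 1.63 and 4.11%. The named probes were picked for large effects within 1 tissue, which favours a difference between tissues. Among those tested, the leaf and root effects differed for 10 of 23 under cold, 1 of 16 under heat and 5 of 26 under salt. The 10 include 1 probe of STWRKY8 whose other probe did not differ (adjusted p 0.39), and 1 of Cyp LOC102586427 at -1.28, where 2 other probes differed by 0.64 and 0.67. The effect at 27 h differed from that at 3 h for 125 probes in leaf cold (64 to 186 without 1 array), 12 in leaf salt (0 to 8), 1878 in root cold, 15 in root heat (3 to 87) and 247 in root salt (97 to 326).

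Salt called more probes with time in leaf (77 at 3 h, 1174 at 27 h) and fewer in root (1884 at 3 h, 217 at 27 h). The spread of the effects was estimated from the covariance of replicates, each minus the no-stress array of its number. Noise that differs between times would leave this spread alike at both times. The ratio of that spread at 27 h over 3 h was 1.91 in leaf and 0.66 in root, the latter barely under the bound of 0.67, while the values of the replicate pairs at both times did not overlap. The median SD within the root salt groups was 0.215 at 3 h and 0.139 at 27 h, while the main fit shares 1 spread over groups. With only the contrast's groups in the fit, root counts were 1040, 353 and 329 at 3, 9 and 27 h. Leaf counts were then 86, 488 and 1219. The size of the fall in root thus depends on the fit. With the no-stress arrays of 3 and 27 h exchanged, the counts still had a ratio of 25.1 in leaf and 0.158 in root, which argues against these arrays as the whole cause. The direct test of 27 h against 3 h called only 12 of 9406 leaf probes, which 6 of 100 splits, the real one among them, reached, and limma called 0 without no-stress 27 h replicate 2, no-stress 3 h replicate 1, salt 27 h replicate 2 or salt 3 h replicates 1 or 2 (580 to 759 at an unadjusted p under 0.05). It called 247 probes in root. Leaving out 1 array gave, for the counts at 3 and 27 h, 42 to 88 and 777 to 986 in leaf and 1176 to 1676 and 87 to 197 in root. A difference of the tissues in the course of the salt response may hold as a hypothesis, with little support from the direct test in leaf. It was found and examined on the same data. No test set the change with time in leaf against that in root, since tissues were compared only on the mean over times.

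Leaf heat gave few calls. Noisy leaf heat arrays are a candidate explanation, and their median SDs within a group were 0.181, 0.167 and 0.195 at 3, 9 and 27 h, against 0.194, 0.216 and 0.182 in leaf cold, which decides nothing. Noise that is independent between replicates would leave their covariance, taken as for salt, unchanged. Yet the highest leaf heat pair had at most 0.603 of the spread of the lowest leaf cold pair of the same time. That argues against such noise as the whole cause. If 1 discordant array hid the response, the pair without it should have a spread over 0.5 of the lowest root heat pair, and if none did, no pair should reach that root pair. The ratios were 0.851, 0.743 and 0.64 at 3, 9 and 27 h and meet both of these bounds, which overlap, so the bounds do not decide. Even the highest pair of each time, which can be free of 1 discordant array, stayed below the lowest root heat and leaf cold pairs. For 1 discordant array this bears on the gap in spread alone, which it would not account for in full. Whether such an array lowered the counts stays open. A smaller response of leaves to this heat treatment stays open as a hypothesis.

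Of the photosynthesis probes in cold roots, 11 of 22 fell at 9 h, and at 27 h 17 of 23 fell and 2 rose (adjusted p = 0.702 with an estimated correlation at both). Shoot tissue mixed by chance into some root samples could give such values. At 9 and 27 h the highest cold array had a median of -0.704, and the no-stress arrays lay between -0.26 and 0.192, so chance mixing would need all 6 cold samples to fall on 1 side. At 3 h the highest cold array was at -0.294, close to the lowest no-stress array of any time, -0.26 at 27 h. Over all no-stress arrays this keeps chance mixing open there. The no-stress arrays of 3 h itself lay higher, at -0.081, 0.0288 and 0.0635, against -0.759, -0.294 and -0.303 under cold. The group's call at 3 h ended without cold replicate 1 (0.161) or no-stress replicates 1 or 3 (0.0544, 0.0572). It had adjusted p = 0.723 with an estimated correlation and 0.0639 with 1 value for each of 10 genes. The criterion, a distance tied to the range of the no-stress arrays, was set after these values had been seen, because an earlier bound, that all cold medians exceed 0.26 in size, was met only narrowly at 0.294. Shoot tissue that differs systematically between treatments, and a change within root cells, were not told apart by these tests. Root salt arrays also lay below 0, between -0.644 and -0.1, partly within the range of the no-stress arrays, and were not tested in this way.

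For the 18 comparisons of a stress with no stress, 3 against 3 arrays allow 10 splits, too few for a share under 0.05, and in each of them 1 split, the real one, gave as many calls. At 3, 9 and 27 h, the highest other split gave 0, 5 and 6 calls in leaf cold against 1572, 2119 and 2074, and 2, 1 and 2 in leaf heat against 63, 17 and 64. Leaf salt gave 0, 4 and 1 against 77, 703 and 1174. Root cold gave 6, 2 and 11 against 1200, 2328 and 3476, root heat 1, 1 and 1 against 638, 519 and 1790, and root salt 1, 1 and 0 against 1884, 381 and 217.

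Of 100 splits drawn for each other test, 1, the real one, gave as many calls for the tissue differences under cold (highest other 646), heat (48) and salt (6). The same held for the time difference in root cold (1588), and for root salt 3 splits gave 247 or more (highest other 589). These shares lie under 0.05 but do not exclude chance, because several tests were made and the splits ignored the replicate numbers. The other splits also mixed tissues or times, which can raise the spread within a group and lower their calls. The shares were over 0.05 for the time differences in leaf cold (6 splits, highest other 1176), leaf salt (6, 359) and root heat (12, 2469), so chance was not excluded there either. In leaf heat limma called 0 probes and 199 had an unadjusted p under 0.05. All 100 splits reach a count of 0 by definition (highest other 451), so the splits decide nothing for leaf heat. Splits with several times the real count point to a structure of the arrays. The splits ignored the replicate numbers. In deviations from the group means, arrays of a tissue and time with 1 number correlated at a mean of 0.108 to 0.243. The mean for other pairs, -0.122 to -0.0544, largely follows from that, since the deviations of a group sum to 0. The likeness of arrays with 1 number may raise some of the other splits. With the number as a block the real counts were 331 in leaf cold, 36 in leaf salt, 50 in root heat and 0 in leaf heat (314 unadjusted). In root heat the highest split gave the later label to heat 27 h replicates 1 and 2 and heat 3 h replicate 1.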

How the results depend on the processing

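The settings chosen only after the data were seen are the first spot of each clone and the group tests without single arrays. The cause of each change was not tested, unless fewer probes or arrays give it. Subtracting array medians moved 0 of 27 counts by over 1.5 times and changed the share of positive calls by between -4.73 and 0.758 percentage points. Of 83 pairs of a named gene and a comparison, all 83 kept their call with medians subtracted, with array weights and with the block, while 21 lost it with only the contrast's groups fitted, 2 against 0, 2 with the first spot of each clone, and 44 of 484 tests without 1 array. None reversed, and 56 kept their call under every planned setting run. Of the 37 group calls, 34 held with medians subtracted, 37 with the block, 18 against 0, 11 with 1 value per gene, 17 without each array in turn and 0 with an estimated correlation, where adjusted p ran from 0.398 to 0.825. Where an array was left out, the group keeps 2 arrays and the spread comes from all groups of the fit. Replicate numbers did not pair the samples by the rule fixed beforehand. In deviations from the group means, only 83 of 108 pairs of arrays with 1 number correlated over 0.1. Yet 68 of 72 arrays lay closest to their own number, so pairing is not excluded, and the main p-values ignore it. The block is given as an alternative alone, and it moved 12 of 27 counts by over 1.5 times. The number of arrays limits the precision, and signal over background was not used here.

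Testing the stress arrays against 0 gave, at 3, 9 and 27 h, 2991, 3949 and 3889 for leaf cold, 886, 682 and 568 for leaf heat, 815, 2757 and 2762 for leaf salt, 2948, 4481 and 5224 for root cold, 2416, 1841 and 3642 for root heat, 3798, 2063 and 1728 for root salt. With the replicate number as a block, counts were 138 for leaf heat 3 h, 46 for leaf heat 9 h, 120 for leaf heat 27 h, 1023 for root heat 3 h, 593 for root salt 9 h, 375 for root salt 27 h, 262 for leaf against root for heat, 542 for leaf against root for salt, 331 for 27 h against 3 h in leaf cold, 36 for 27 h against 3 h in leaf salt, 50 for 27 h against 3 h in root heat, 380 for 27 h against 3 h in root salt. With only the contrast's groups fitted, counts were 1296 for leaf cold 9 h, 0 for leaf heat 9 h, 0 for leaf heat 27 h, 257 for root heat 3 h, 308 for root heat 9 h, 125 for root heat 27 h, 1040 for root salt 3 h, 329 for root salt 27 h, 57 for 27 h against 3 h in leaf salt, 0 for 27 h against 3 h in root heat, 156 for 27 h against 3 h in root salt. Where limma called 0 there, 896 probes in leaf heat at 9 h, 1080 at 27 h and 754 for the time difference in root heat had an unadjusted p under 0.05. With only probes measured on every array, counts were 25 for 27 h against 3 h in root heat.

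With array weights, whose estimation stopped before convergence for 2 of the 3 fits, counts were 5015 for leaf cold 27 h, 181 for leaf heat 3 h, 244 for leaf heat 9 h, 516 for leaf heat 27 h, 180 for leaf salt 3 h, 1954 for leaf salt 9 h, 2365 for leaf salt 27 h, 1364 for root heat 9 h, 1375 for root salt 9 h, 641 for root salt 27 h, 293 for leaf against root for heat, 904 for leaf against root for salt, 1606 for 27 h against 3 h in leaf cold, 135 for 27 h against 3 h in leaf salt, 44 for 27 h against 3 h in root heat, 498 for 27 h against 3 h in root salt. With only the first spot of each clone, chosen after seeing the data, counts were 42 for leaf heat 27 h, 65 for leaf against root for heat, 7 for 27 h against 3 h in leaf salt, 4 for 27 h against 3 h in root heat, 149 for 27 h against 3 h in root salt. Leaving out 1 array at a time gave counts of 895 to 1612 for leaf cold 3 h, 1374 to 2087 for leaf cold 27 h, 7 to 63 for leaf heat 3 h, 1 to 14 for leaf heat 9 h, 9 to 126 for leaf heat 27 h, 42 to 88 for leaf salt 3 h, 300 to 654 for leaf salt 9 h, 777 to 986 for leaf salt 27 h, 762 to 1096 for root cold 3 h, 283 to 599 for root heat 3 h, 138 to 428 for root heat 9 h, 703 to 2231 for root heat 27 h, 1176 to 1676 for root salt 3 h, 192 to 266 for root salt 9 h, 87 to 197 for root salt 27 h, 75 to 263 for leaf against root for heat, 64 to 186 for 27 h against 3 h in leaf cold, 0 to 8 for 27 h against 3 h in leaf salt, 3 to 87 for 27 h against 3 h in root heat, 97 to 326 for 27 h against 3 h in root salt.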

Other observations

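The dye test had its bounds set before the result was seen. In leaf at 27 h of cold, GAPDH, of glycolysis, rose by up to 1.34 (SE 0.24, limma adjusted p 0.000204) and PK, pyruvate kinase, by 0.88 (SE 0.13). Of 15 glycolysis probes there 8 rose, 2 fell and 5 did not pass (0.0128, and adjusted p = 0.702 with an estimated correlation), and the call ended without cold replicate 1 (0.0536) or 3 (0.0776) or with 1 value for each of 6 genes (0.232). FDH rose by 0.88 under cold and 0.96 under salt (SE 0.24) in leaf at 27 h. Of PHA2, a plasma membrane proton pump, 3 probes rose in leaf at 27 h of cold, by up to 0.71 (SE 0.22), and the fourth did not pass (-0.24, adjusted p 0.147). At 9 h that probe fell (-0.44) while the other 3 rose. Of the ion transport and proton pump probes in root at 27 h of cold, 4 of 7 rose, 0 fell and 3 did not pass, without a group call (adjusted p 0.277).

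InvCD141 was 1.73 higher in root at 27 h of cold (SE 0.42, limma adjusted p 0.0016), and at -0.56 in leaf, which did not pass (adjusted p 0.246). SHKA, of the shikimate pathway, rose by 1.04 in leaf at 27 h of cold (SE 0.29) and by 0.64 in root at 3 h of salt (SE 0.17). Over all probes tested in root at 27 h of cold, 38.89% were called (1818 higher, 1658 lower). Close to that share, antioxidant and alternative respiration probes there gave 1 higher, 3 lower and 7 not passing of 11 (adjusted p 0.454). Translation probes gave 0 higher, 3 lower and 5 not passing of 8 (adjusted p 0.131), also close to it. These genes were picked after their values were seen.

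The no-stress arrays, which compare control with control, differed from 0 for up to 462 probes. A dye effect that is specific to the probe may account for part of this, and no dye swap was made. It predicts alike values in leaf and root, which share no RNA, and the mean no-stress values of both tissues correlated across probes at 0.556, where genes are not independent replicates. By time the correlation was 0.331, 0.466 and 0.516 at 3, 9 and 27 h. Control plants that differ from the reference plants in both tissues could give alike values too, so the correlation does not single out dye. The counts different from 0 were not alike, at 6, 71 and 1 in leaf and 462, 295 and 133 in root.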
